A study of Homo sapiens with 2 samples.

How the data were processed

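Total RNA from 2 cultures of HCT116, a human colorectal cancer cell line, was measured on 3′ expression arrays with biotin label, 1 array for each culture. Per the labels, the first culture is the wild-type line named with GFP (HCT116-GFP) and the second is the line made to over-express CPEB4 with a lentiviral vector (HCT116-CPEB4). Whether the HCT116-GFP cells were transduced with a vector of their own is not given in the sources used here. The groups were taken from the sample titles, and 0 columns of the value table were left unused. Nothing in the labels describes a second culture of either group, so the comparison has no replicate, no p-value was computed, and the number of arrays limits the precision of every value.

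The authors' deposited table holds 1 linear intensity for each probe set and array. Partek is named in the submitters' processing notes, without a version or a stated role. The summarisation of probes into probe sets, the background correction and the scaling between arrays are not given in the sources used here. The values themselves are positive, run from 0.206 to 48344 on the HCT116-GFP array and from 0.275 to 45176 on the HCT116-CPEB4 array, and have a trimmed mean of 500.1 on both arrays when 2% of the values are removed at each end. Equal trimmed means are a property of arrays scaled to a common overall level. Such a scaling leaves differences that depend on brightness in place, and dim values stay noisy on a ratio scale. Detection calls were not used here, so brightness was judged by the filter described next.

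Probe sets were named through a platform annotation table, with symbols updated by Entrez identifier to the NCBI RefSeq gene table of assembly GRCh38.p14, which was used for names only. Of 54675 probe sets, 41097 have 1 gene symbol, 1801 have several and 11777 are unnamed here. The identifiers of 41043 probe sets with 1 gene were found in the RefSeq table. Probe sets with several genes or none were left out, as were 62 manufacturer's control probe sets, which were examined apart. No genomic position of a probe set was given in the sources used, so no coordinates are reported and the part of a transcript that a probe set reads is not known here. Some members of the gene lists are not analysed here because no probe set is paired with them alone.

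The log2 of each intensity was taken without a pseudocount, and the difference was computed as HCT116-CPEB4 minus HCT116-GFP. A probe set was kept if the higher of its 2 intensities reached 60.8, the 50th percentile of all values (the dim filter), which left 25010 probe sets and 13704 genes. Each gene took the value of its kept probe set with the highest mean log2 intensity. A gene was counted as higher or lower at a difference of 2-fold or more, which is a rule of size and not a test. Disagreement between probe sets of a gene was measured as the absolute gap between the log2 differences of its 2 brightest kept probe sets.

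The 36 gene lists were fixed before the data were examined. They cover the CPEB family, poly(A) tail and mRNA decay regulators, stress responses, cell cycle, apoptosis, adhesion and mesenchymal markers, WNT, MYC, YAP, NF-kB and interferon targets, metabolism, translation, protein turnover, colon cell types, reference genes and markers of other cell types. The median log2 difference of each list with at least 5 measured members was placed among 10000 random gene lists of the same size, matched on mean log2 intensity in 20 bins with a fixed seed. A list is called outside when its median lies beyond the central 95% of those random lists. The percentile is a description of these arrays, since genes are not replicates. If genes were independent, which they are not, 1.7 of the 34 lists with a percentile would lie outside by chance.

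The rule for named genes was also fixed beforehand. It takes the CPEB family, the 15 genes with the highest and the 15 with the lowest difference whose kept probe sets all share a sign, 4 members of each list outside its random lists, 2 members of each other list, and the ACTB, GAPDH and spike-in controls. Uncharacterised loci, open reading frame names and long non-coding RNA genes were passed over, but pseudogenes were not, so CLIC1P1, TRPC2 and POTEKP are among the genes named. Because the 15 extremes at each end turned out to be mostly dim, the 15 extremes at each end under a stricter filter, 377 intensity units or the 75th percentile, were added after the values were seen. Further genes from the lists are given as examples of their group and were also chosen after their values were seen.

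The procedure was tested on simulated arrays of 13751 genes for the comparison of HCT116-CPEB4 with HCT116-GFP, with noise set in each brightness bin from the spread of the measured differences themselves. At 2-fold it recovered 197 of 198 genes simulated at a 4-fold difference. Among the other genes, unchanged except for the shifted list below, 469 passed 2-fold upwards and 485 downwards. Under the stricter filter 3 of these other genes passed in each direction, out of 8338 genes. The noise was drawn from a normal distribution with a robust spread, which leaves out extreme differences, so these 3 may be too few. A list of 29 members shifted by 0.5 on the log2 scale lay at percentile 100, and 2 of 40 unshifted lists lay outside. The unshifted lists were random genes with independent noise. Their count does not tell how often lists of genes that vary together lie outside.

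The alternatives were quantile normalization, median centring, loess of the difference on brightness (span 0.3, 3 robustness iterations), no dim filter, the stricter filter, the mean over probe sets, removal of probe sets marked _x_at or _s_at (possible cross-hybridisation), agreement of all probe sets, size rules of 1.5-fold and 3-fold, pseudocounts of 16 and 64, and random lists without matching. Among the 8 alternatives that apply to the lists, median centring moves all genes by the same amount. It could therefore hardly change whether a list is outside. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.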

Results

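Gene expression was compared between HCT116-GFP and HCT116-CPEB4 cells, with 1 array for each. CPEB4 is an RNA-binding protein that recognises cytoplasmic polyadenylation elements in 3′ untranslated regions and regulates poly(A) tails and translation. The comparison asks which transcripts differ in colorectal cancer cells made to over-express it. Both arrays had 54675 probe sets, with a median intensity of 60.6 on the HCT116-GFP array and 61.1 on the HCT116-CPEB4 array. All differences below are log2 values of HCT116-CPEB4 minus HCT116-GFP, and none has a replicate check.

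CPEB4 itself was not higher on the array labelled HCT116-CPEB4. Its brightest probe set read 731 on the HCT116-GFP array and 628 on the other, a difference of −0.22. The remaining probe sets of CPEB4 read 758 against 558 (−0.44), 183 against 174 (−0.08) and, under the dim filter, 60.1 against 21.0 (−1.52). These differences stood at percentiles 34.7, 24.4, 44.6 and 8.74 of all probe sets. The positions of these probe sets were not given in the sources used, and a probe set in a 3′ untranslated region that the introduced sequence lacks would check nothing. The direction of every difference that follows rests on the labels, and the second sample is therefore called the array labelled HCT116-CPEB4, or the CPEB4-labelled array.

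The other family members were no higher at their brightest probe sets. CPEB2 read 408 against 277 (−0.56), with −0.51 at its second kept probe set. CPEB3 read 218 against 161 (−0.43), but its 4 probe sets ran from −1.76 to 0.78. Both probe sets of CPEB1 were under the dim filter. The median of the 3 measured family members was −0.43.

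Genes induced by interferon, the antiviral cytokine family, stood apart from all other groups. Of 36 measured interferon-stimulated genes, 35 were higher on the CPEB4-labelled array, 25 of them by 2-fold or more, and the median difference was 1.74, or 3.34-fold. IFIT1, which binds viral RNA lacking a host cap, read 444 on the HCT116-GFP array and 5865 on the CPEB4-labelled array, and IFIT3 read 133 and 2063 (3.95), with 1.78 at its other probe set and 2.87 as their mean. OASL differed by 3.22, IFI6 by 3.17 and IFI27 by 3.03, and the viral RNA sensor IFIH1 read 309 and 2469.6, with 1.83 at its other probe set. ISG15, a ubiquitin-like modifier, was already bright at 7152 and read 21379 on the CPEB4-labelled array.

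**Figure D1:**
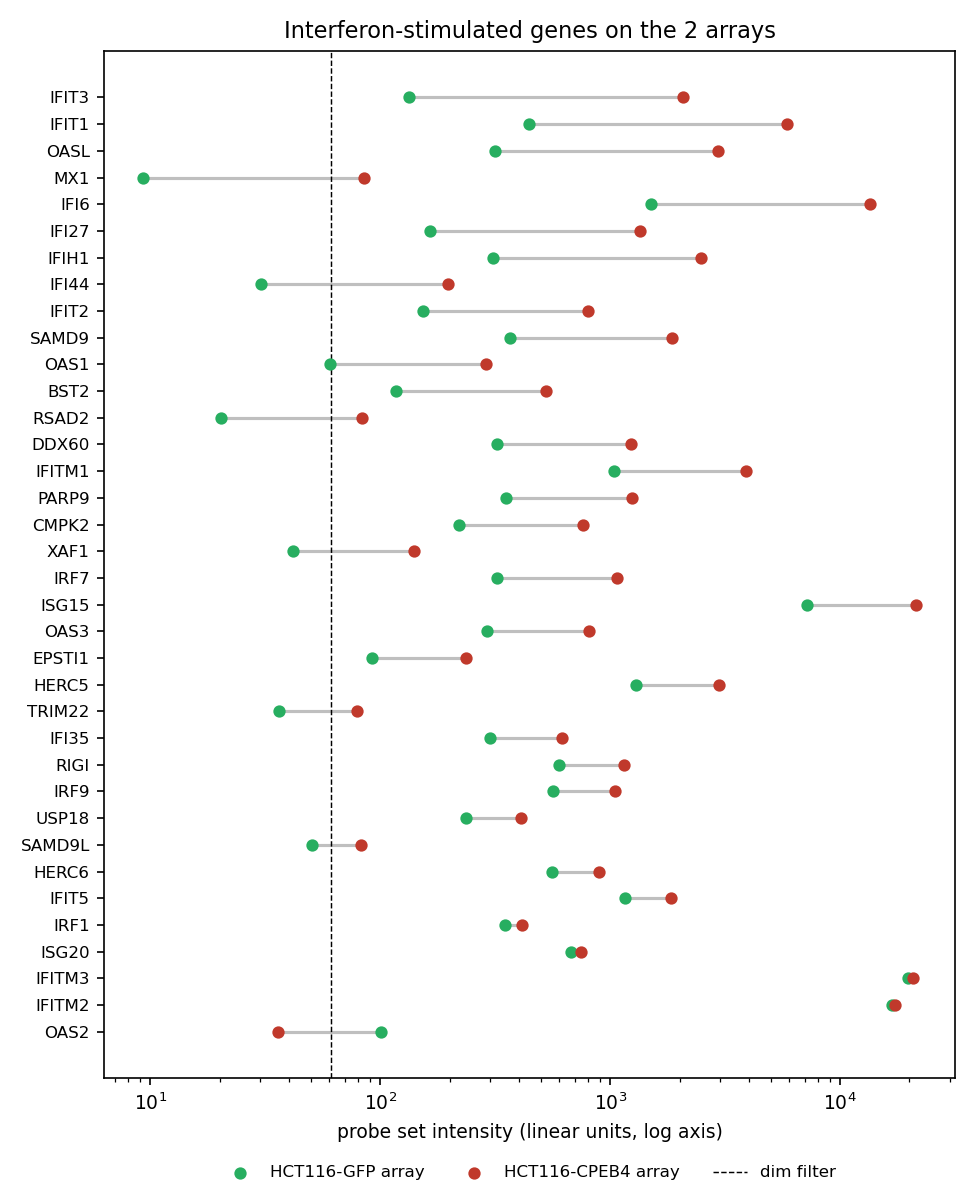
Probe set intensity (linear units on a log axis) of the 36 measured interferon-stimulated genes on the HCT116-GFP array (green) and the HCT116-CPEB4 array (red), with 1 array per group and a dashed line at the dim filter of 60.8. The red point lies to the right of the green point in 35 of the 36 genes, and OAS2 is the exception.

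The difference extended to the transcription factors IRF7 (1.73) and IRF9 (0.89) and to the sensor RIGI (0.93). It was small for IRF1 (0.25), ISG20 (0.14), IFITM3 (0.07) and IFITM2 (0.04). OAS2 was the 1 member in the other direction, at 101 against 35.7. MX1, a GTPase that blocks several viruses, read 9.29 and 85.1, so its GFP value lay under the dim filter. Across the list, 8 members had an array under that filter, and 19 members passed 2-fold with both arrays at or above it. The list median lay at percentile 100 of its random lists, whose central 95% ran from −0.13 to 0.13, and it stayed outside in all 8 alternatives, between 1.66 and 1.77.

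Class I antigen presentation genes, many of which respond to interferon, were also higher as a group. Their median was 0.19 over 15 genes (percentile 99.3), with 12 above 0. The transcriptional activator NLRC5 read 84.8 and 251, and the peptide transporter TAP1 read 1327 and 2311. The heavy chain genes differed little, with HLA-B at 0.09 and HLA-C at 0.07. The peptidase ERAP2 differed by 0.72, with its GFP value under the dim filter. ERAP1 differed by 1.18 at its brightest probe set and by −0.60 when probe sets marked for possible cross-hybridisation were removed, so its direction is not settled. The list remained outside in 6 of the 8 alternatives, over which its median ran from 0.15 to 0.34.

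NF-kB targets and cytokines had a median of 0.29 over 22 genes (percentile 99.5) and went both ways. The neutrophil chemokines CXCL1 and CXCL2 read 130 and 84.8 on the HCT116-GFP array against 349 and 235. CXCL10, a chemokine induced by interferon, read 5.80 against 97.7, and CXCL5 read 21.9 against 61.7, both from under the dim filter. The inhibitor NFKBIA differed by 0.49. In the other direction, IL1B (−2.21) and NFKB2 (−1.35) were lower by more than 2-fold, with both under the dim filter on the CPEB4-labelled array. IL11 had probe sets at −1.40 and 2.31, so its direction is not settled. This list was outside in 6 of the 8 alternatives.

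Genes of DNA replication and the G1/S transition were higher on the CPEB4-labelled array by a smaller and more even amount. Of 31 genes, 27 lay above 0, and the median was 0.32 (1.25-fold, percentile 100). CDC25A, a phosphatase that activates cyclin-dependent kinases, read 223 against 726, with 0.44 at its other probe set. The S-phase cyclin CCNE2 differed by 0.74, the clamp loader subunit RFC2 by 0.71, and the origin licensing factors CDT1 and CDC6 by 0.68 and 0.66. GINS2, a subunit of the replicative helicase, differed by 0.83, although its 3 probe sets ran from −0.58 to 1.10. PCNA read 14206 against 14199, and LIG1 was lower (−0.27). Genes of G2/M and mitosis had a median of 0.03 over 32 genes (percentile 72.2), with KIF20A at −0.50 and CDK1 at −0.55, although the 4 probe sets of CDK1 ran up to 0.14 and averaged −0.12. The G2/M median was −0.01 with the mean over probe sets. The G1/S list stayed outside in all 8 alternatives, between 0.31 and 0.35.

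Genes of ribosome biogenesis, the proteasome and the respiratory chain were higher as groups by small amounts, with members in both directions. MYC targets and ribosome biogenesis genes had a median of 0.09 over 26 genes (percentile 98.4), led by RRS1 (0.51), BYSL (0.48), NOP58 (0.39) and PES1 (0.38). MYC itself was lower (−0.32), as were CAD (−0.44), ODC1 (−0.28) and NPM1 (−0.19). Without the members shared with another list outside its random lists, 15 of 24 genes lay above 0 and 9 below. Above and below 0 lay 19 and 8 of the proteasome genes, and 22 and 10 of the respiratory chain genes. Proteasome genes had a median of 0.08 over 27 genes (percentile 99.2), led by PSMC2 (0.36), PSMD11 (0.29), PSMC6 (0.27) and PSMD12 (0.26). Nuclear genes of the mitochondrial respiratory chain had a median of 0.06 over 32 genes (percentile 99.2), with SDHC at 0.37, NDUFV2 at 0.28, NDUFB3 at 0.27 and NDUFA1 at 0.25. These lists stayed outside in 6, 5 and 5 of the 8 alternatives, in that order. Their medians over the alternatives ran from 0.07 to 0.19, from 0.06 to 0.10 and from 0.05 to 0.11.

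**Figure D2:**
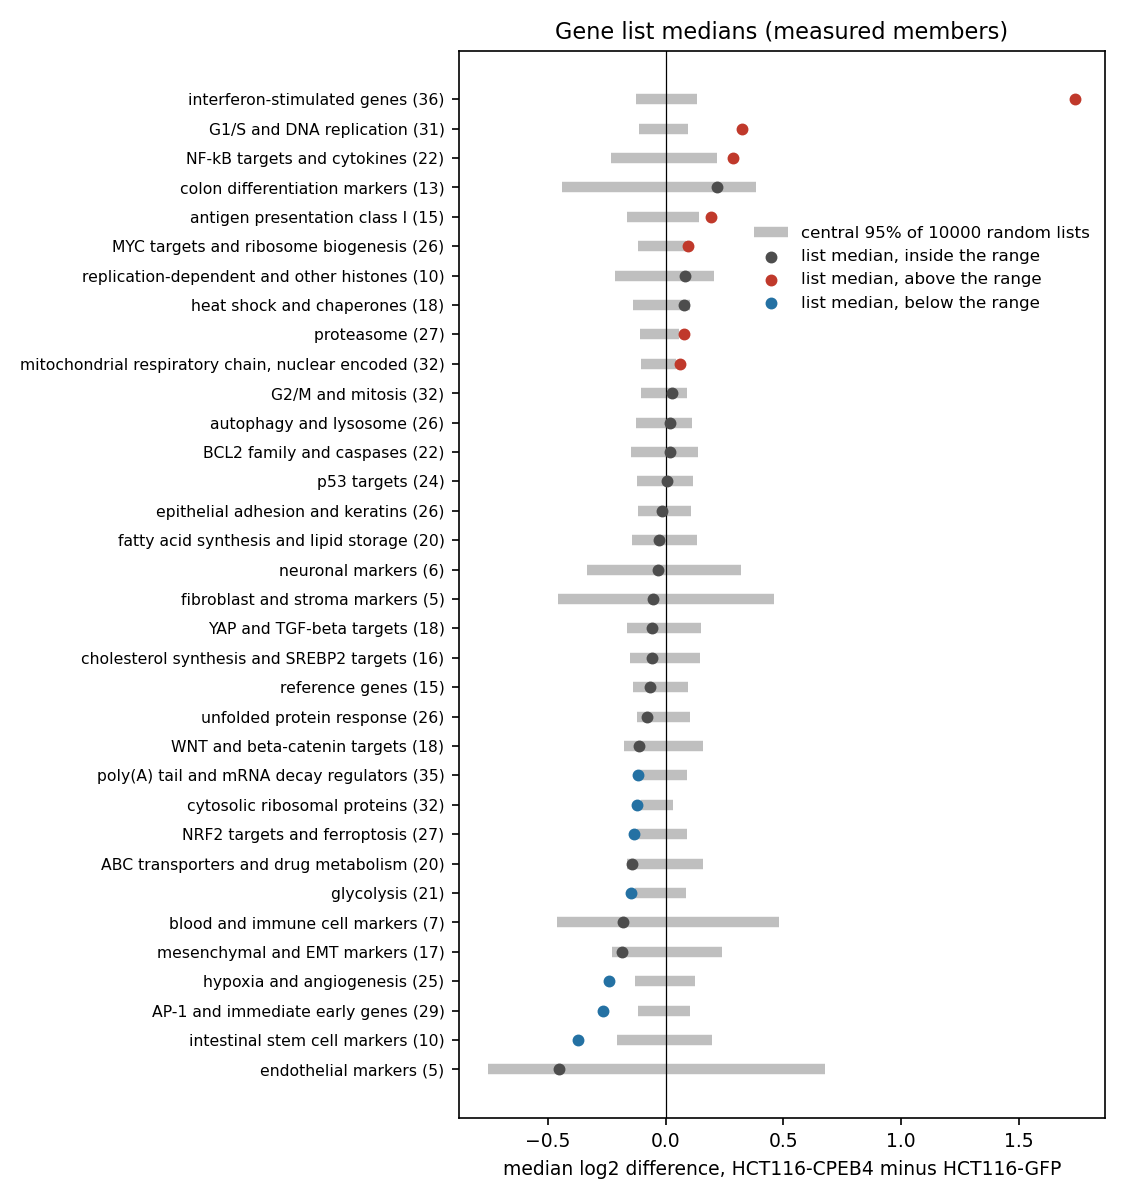
Median log2 difference, HCT116-CPEB4 minus HCT116-GFP, of the 34 gene lists with at least 5 measured members (number of members in brackets), against the central 95% of 10000 random lists matched on brightness (grey bars), with 1 array per group. The interferon-stimulated genes lie at 1.74, 7 lists lie above their bar (red) and 7 below it (blue).

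Hypoxia and glycolysis genes were lower on the CPEB4-labelled array. Of 25 hypoxia and angiogenesis genes, 17 lay below 0, with a median of −0.24 (percentile 0.01). DDIT4, an mTORC1 inhibitor induced by stress, read 7878 on the HCT116-GFP array and 3163 on the other (−1.32). ANGPTL4 differed by −0.83, NDRG1 by −0.71, the collagen prolyl hydroxylase P4HA1 by −0.63 and VEGFA by −0.30, with VEGFA probe sets up to 0.09. VEGFB read 68.1 against 18.1, with the second value under the dim filter. In the other direction, 8 hypoxia and angiogenesis genes lay above 0, among them THBS1 (0.46), HIF1AN (0.38) and ADM (0.28). Glycolysis genes had a median of −0.15 over 21 genes (percentile 0.98), with ALDOC at −0.71, the glucose transporter SLC2A3 at −0.60, PFKL at −0.43 and GPI at −0.33. The hypoxia list stayed outside in all 8 alternatives, between −0.25 and −0.21, and the glycolysis list in 5. After quantile normalization the glycolysis median was −0.07 and inside (percentile 10.3).

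Immediate early genes, which respond within minutes to growth factor signalling, were lower in 21 of 29 cases. Their median was −0.27 (percentile 0.00, that is, below all of the random lists). The transcription factor EGR1 read 5369 against 3254, and its 3 probe sets ran from −0.79 to −0.40. FOS differed by −0.63, CCN2 by −0.46 and ETV5 by −0.46, although 1 of the ETV5 probe sets read 0.79. The MAP kinase phosphatases DUSP4 and DUSP6, which are induced by ERK signalling, differed by −0.40 and −0.33. DUSP2 (0.76) and JUNB (0.42) were higher. This list stayed outside in all 8 alternatives, between −0.31 and −0.16.

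Markers of intestinal stem cells had a median of −0.37 over 10 measured genes of the 19 listed (percentile 0.03), with 8 below 0 and 2 above. LGR5, ASCL2, OLFM4 and SMOC2 were not among the measured genes. PTPRO (0.69) and CDX2 (0.22) were higher. The transcription factor SOX9 read 7286 against 4693 (−0.63), the surface protein CD24 differed by −0.49 with probe sets up to 0.25, and the WNT inhibitor RNF43 differed by −0.49. TERT read 107 against 58.0, the second under the dim filter. The list was outside in 7 of the 8 alternatives. Its median was −0.22 with the mean over probe sets, and without cross-hybridising probe sets it was −0.16 over 6 genes and inside (percentile 13.8). Among WNT targets the median was −0.11 over 18 genes (percentile 11.7), and the members farthest from 0 were the dim LEF1 (2.60) and NKD1 (−2.41), which read 1.61 at its other probe set.

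NRF2 target and ferroptosis genes had a median of −0.14 over 27 genes (percentile 1.42). SLC7A11, the cystine transporter, read 1390.1 against 710.3 (−0.97), with its 3 probe sets between −1.05 and −0.03. AKR1C2 differed by −0.34 and TXNRD1 by −0.30, and the iron exporter SLC40A1 by −0.90 with 1.07 at its other probe set. Regulators of the poly(A) tail and of mRNA decay had a median of −0.12 over 35 genes (percentile 1.74), which was −0.18 with the mean over probe sets and −0.05 and inside (percentile 30.1) without cross-hybridising probe sets. Among them were the deadenylase subunits CNOT8 (−0.57, with probe sets up to 0.02) and PAN2 (−0.45), the decapping factor DCP1A (−0.39) and the cleavage factor CPSF1 (−0.66, its second value under the dim filter). Of the 35 genes, 25 lay below 0 and 10 above, with the highest at 0.82. Cytosolic ribosomal protein genes were lower in 30 of 32 cases, with a median of −0.12 (percentile 0.55), RPS7 at −0.27, RPS14 at −0.24, RPL3 at −0.21 and RPL8 at −0.20. The ribosomal median was −0.01 after quantile normalization and then lay inside its random lists. These 3 lists were outside in 4, 6 and 5 of the 8 alternatives.

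The unfolded protein response list lay inside its random lists, at −0.08 over 26 genes (percentile 10.8), although it held a large single difference. DDIT3, the stress-induced transcription factor CHOP, read 2456 against 694 (−1.82), and its activator ATF4 differed by −0.50, while XBP1 was higher (0.56). Heat shock and chaperone genes had a median of 0.08 (percentile 93.5), with DNAJA1 at 0.63 and the dim CRYAB at −1.90. That median was −0.05 with the mean over probe sets and −0.12 without cross-hybridising probe sets, and under the stricter filter it was 0.12 and outside (percentile 98.5). Targets of p53 had a median of 0.01 (percentile 51.3) and just below 0 after each scaling, with PLK3 at 0.56 and ZMAT3 at −0.43, and BCL2 family and caspase genes had a median of 0.02 (percentile 56.8), with BCL2 at −0.91 and the dim BMF at 1.29. The BCL2 and caspase median was 0.18 (percentile 95.8, inside) without cross-hybridising probe sets, −0.03 with the mean over probe sets and −0.02 under the stricter filter, and the p53 median was −0.09 with the mean over probe sets, so neither direction is settled. Autophagy and lysosome genes had a median of 0.02 (percentile 63.8), with ATP6V0D1 at 0.83 and GABARAPL1 at 0.57, and that median was −0.11 without cross-hybridising probe sets and −0.03 under the stricter filter. Histone genes had a median of 0.08 (percentile 79.7), with H3-3A at −0.69 and the dim H4C8 at −0.48, and the median was −0.01 with the mean over probe sets.

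Epithelial adhesion and keratin genes had a median of −0.02 (percentile 41.4), which was 0.05 after quantile normalization and 0.03 after loess, with the desmosomal genes DSP at −0.60 and DSC2 at −0.49. Mesenchymal markers had a median of −0.18 (percentile 4.97), with SPARC at −1.52 and MMP2 at 23.0 against 65.0, each with an array under the dim filter. The mesenchymal median was −0.06 (percentile 37.5) without cross-hybridising probe sets. Targets of YAP and TGF-beta had a median of −0.06 (percentile 28.6), with TGFB2 at 0.72 and LTBP2 at −0.95 and 0.75 on its 2 probe sets. With the mean over probe sets that median was 0.17 and outside (percentile 98.1), so the direction of this list is not settled. Colon differentiation markers had a median of 0.22 (percentile 87.9), and their extremes CDX1 (2.47) and CEACAM7 (1.35) were dim on the HCT116-GFP array. That median was −0.24 with the mean over probe sets and −0.23 without cross-hybridising probe sets, while without the dim filter it was 0.57 and outside (percentile 99.9), so its direction is not settled either.

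Lipid and drug metabolism lists also lay inside. Cholesterol synthesis genes had a median of −0.06 (percentile 21.8), with STARD4 at −0.57 and NSDHL at 0.28. Fatty acid synthesis and lipid storage genes had a median of −0.03 (percentile 36.1), with the desaturase FADS2 at 238 against 68.4 (−1.80) and SREBF1 at −0.52, and that median was 0.03 without cross-hybridising probe sets. ABC transporter and drug metabolism genes had a median of −0.14 (percentile 5.52), with the dim CYP1A1 at −2.08 and CYP1B1 at −0.78.

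Markers of other cell types lay inside their brightness-matched random lists and were mostly dim. The medians were −0.06 for fibroblast and stroma markers (percentile 38.2), −0.18 for blood and immune cells (20.3), −0.45 for endothelium (11.5) and −0.03 for neurons (42.9), and the 4 measured kidney and HEK293 markers had a median of 0.31. With the mean over probe sets the blood and immune median was 0.45 (percentile 94.5), that of fibroblasts −0.34 and that of neurons 0.08, and against unmatched random lists the endothelial list was outside (percentile 1.31). Their farthest members were DCN (1.23) and COL1A1 (0.45), CSF1R (1.38) and CD79A (−0.74), ERG (−2.50) and PECAM1 (−0.66), ELAVL4 (0.68) and MAP2 (−0.30), and AQP1 (1.46) and SIX2 (−0.83), and DCN, CSF1R, ERG, ELAVL4 and AQP1 each had an array under the dim filter. Reference genes had a median of −0.07 (percentile 27.035), with TBP at −0.41 and YWHAZ at −0.19. The ACTB control probe sets had a median of −0.16, with −0.01 at the 3′, −0.16 at the middle and −0.34 at the 5′ probe set. Those of GAPDH had a median of −0.13, which after quantile normalization was −0.01 with 1 of the 3 probe sets above 0. The ratio of 3′ to 5′ signal grows with RNA degradation or short labelling products. For ACTB it was 8.23 on the HCT116-GFP array and 10.3 on the CPEB4-labelled array, and for GAPDH 0.989 and 1.04. The ACTB ratio was thus far above 1 on both arrays and higher on the CPEB4-labelled array. Whether RNA quality or labelling moved the small list medians was not tested.

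Over all 13704 genes, 487 were higher and 527 lower by 2-fold or more, and most were dim. In 398 of the higher and 457 of the lower genes the dimmer array was under the dim filter. In the simulated arrays, whose noise was taken from these arrays, 469 and 485 genes not simulated at a 4-fold difference passed the same rule. Real differences enter that noise too, so counts near 487 and 527 are partly built in and do not show which genes are noise. The median gap between probe sets of a gene was 0.53 for the dimmest of 3 equal groups of genes with several probe sets, 0.28 for the middle group and 0.16 for the brightest. Probe sets disagreed in sign for 22 of the genes named by the fixed rule, among them RPS14 (up to 1.16), PLK3 (down to −0.85), COL1A1 (down to −3.05), PSMC2 (down to −0.33), SDHC (down to −0.30), DSC2 (up to 0.24), SREBF1 (up to 0.18) and PFKL (up to 0.12). The 15 highest genes under the fixed rule included CXCL10, IFIT3 and IFIT1, and the other 12 were WNK3, KRTAP3-1, KIAA0754, SLC4A9, SLC22A9, GLYATL1, FASLG, FAM186B, H3C8, KLF17, SIRPB1 and PRSS50. The 15 lowest were ZIC4, GRHL3, PLVAP, MYO1A, TRPV2, ADGRL2, IQCF1, RAB43, CLIC1P1, ADAMTS10, TRPC2, UBAP1L, CCDC7, WNK4 and CABP1. The dimmer value lay under the filter in 13 of the 15 highest and in 15 of the 15 lowest, and 14 and 15 of them had 1 probe set. WNK3, the highest, read 3.28 against 86.5, and ZIC4, the lowest, read 65.6 against 1.95. Without the dim filter the values of SLC4A9 (−0.55) and ZIC4 (0.12) changed sign.

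**Figure D3:**
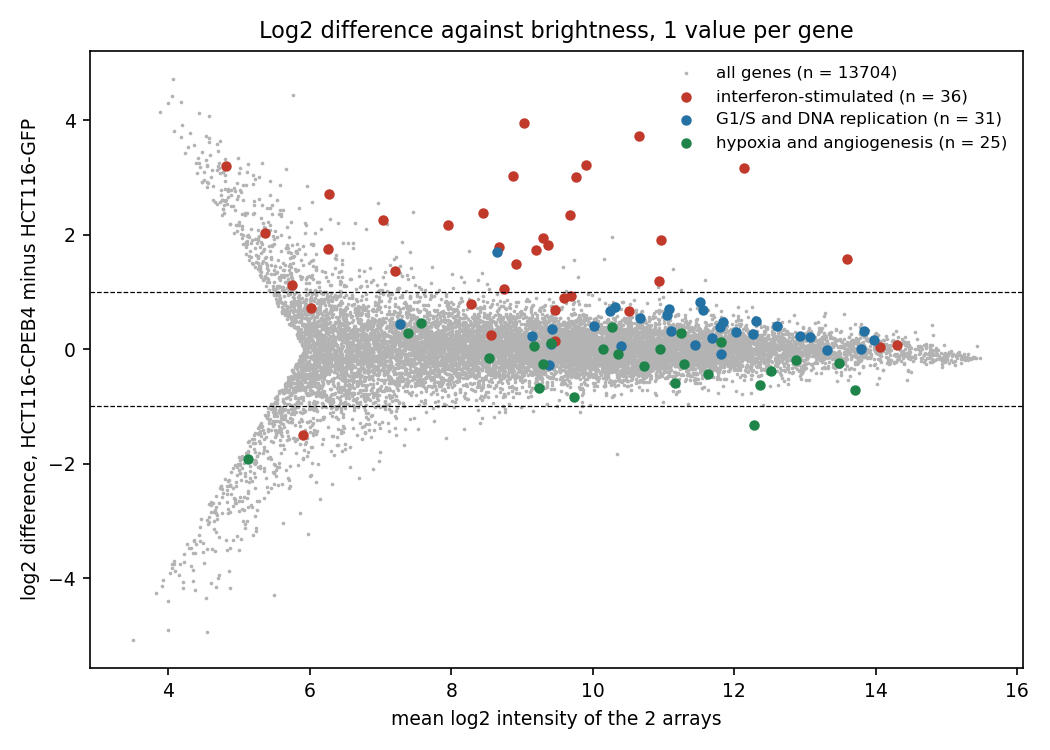
Log2 difference, HCT116-CPEB4 minus HCT116-GFP, against the mean log2 intensity of the 2 arrays for 13704 genes (grey), with interferon-stimulated genes (red, 36), G1/S and DNA replication genes (blue, 31) and hypoxia and angiogenesis genes (green, 25), and dashed lines at 2-fold. The grey points fan out at low intensity, and the red points above 2-fold continue into the bright range.

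Among the 8463 genes that passed the stricter filter, 40 were higher and 14 lower by 2-fold or more. Of the 40 higher genes, 19 were on the interferon list, which had 28 members in this range, and 0 of the 14 lower genes were. The filter uses the higher of the 2 values, so the difference itself enters this choice. IFIT3, IFI27, IFIT2 and BST2 reached the filter only on the CPEB4-labelled array, and the lower gene UTS2R only on the HCT116-GFP array. The 15 highest were OAS1, IFIT3, IFIT1, OASL, IFI6, IFI27, IFIH1, IFNL2, IFIT2, SAMD9, BST2, SP110, DDX60, IFITM1 and PARP9. The interferon lambda gene IFNL2 (77.0 against 404.4) and the nuclear body gene SP110 (625 against 2433, with all 4 of its probe sets higher, by up to 2.13) were the 2 not on the list. OAS1 read 60.2 against 288 (2.26) at the probe set used in the main analysis and 10.6 against 466 at the only one kept by the stricter filter, so its lower value was dim in each. The lowest were DDIT3, UTS2R (−1.55), XYLT2 (−1.40), DDIT4, MYCL (−1.30), SESN3 (−1.20), POTEKP (−1.18), RDM1 (−1.10), SEPTIN6 (−1.10), CRISPLD2 (−1.09), NME4 (−1.08), MAP1B (−1.06), KMT5A (−1.04), ATAD3A (−1.02) and ATAD3B (433 against 217), each on 1 probe set. ATAD3A and ATAD3B are close paralogs read by probe sets marked for cross-hybridisation, and POTEKP is an actin-like pseudogene, so their values are uncertain.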

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

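The tests of dim probe sets, immune cells, array handling, glycolysis after quantile normalization, cell cycle phase, culture density, probe set position and swapped labels were chosen after the results were seen. The result singled out lies in the spike-in control probe sets, which no comparison above uses. The poly(A) spike-ins, bacterial transcripts added to the RNA before labelling, were higher on the array labelled HCT116-CPEB4 in 23 of 24 probe sets, with a median difference of 0.42. These probe sets read only the dap, lys, phe and thr transcripts, each several times, so they are not 24 separate checks. The hybridisation spike-ins, added after labelling, had a median of 0.06 over 18 probe sets. Quantile normalization, median centring and loess left the poly(A) spike-in median between 0.40 and 0.41. The interferon median (1.74) is larger than this, while those of G1/S (0.32), the proteasome (0.08) and the respiratory chain (0.06) are smaller. For the smaller medians, higher therefore means against the overall level of the arrays and not against these spike-ins.

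Interferon-stimulated genes were higher on the array labelled HCT116-CPEB4, by a median of 1.74, which was 1.73 after loess removed the trend with brightness and so argues against that trend as the cause. Noise of dim probe sets as the whole cause is argued against by the 12 members that reached the 75th percentile on the HCT116-GFP array. All 12 were higher, 5 by 2-fold or more, with a smaller median of 0.91 against −0.15 to 0.15 for random lists of genes chosen alike. Blood or immune cells would bring their own abundant transcripts, but the brightest of 36 probe sets for their markers read 287 on the CPEB4-labelled array and none gained more than 118 units, while ISG15 went from 7152 to 21379 (the median of the marker list, −0.18, turns to 0.45 with the mean over probe sets and decides nothing). Intensities of different probe sets are not on a common scale, so the contrast with ISG15 is only rough. A response of the interferon gamma type would move genes that lean on gamma. That list, fixed before its values were seen, had a median of 0.13 over 11 measured genes of 18, with 7 above 0 and 4 below. The dim CIITA differed by 0.93, and HLA-DRA by −0.50 with 1.39 at its other probe set. The median therefore argues only weakly against such a response. Culture or array handling that differed between the samples cannot be told apart from any other difference between the labelled samples with 1 array per group, and whether the HCT116-GFP cells carried a vector is not given in the sources used here, so CPEB4, whose own probe sets were not higher, and the lentiviral vector both stay open and untested.

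DNA replication genes were higher, and hypoxia, glycolysis and immediate early genes lower, on the same array. After loess the medians were 0.35 for G1/S, −0.21 for hypoxia, −0.22 for immediate early genes and −0.10 for glycolysis. Except for glycolysis, these sizes argue against a trend with brightness as the whole cause. That 4 of the 4 lists stayed outside, on the same side, after loess adds little, because their random lists were already matched on brightness. After quantile normalization 3 of the 4 stayed outside, and the glycolysis median was then −0.065 (percentile 10.3, inside), so scaling stays open for glycolysis. More cycling cells in all phases would move mitotic genes as well, but the G2/M median was 0.027 against 0.32 for G1/S. A different density or medium age of the 2 cultures could shift all 4 lists together, and with 1 array per group it cannot be told apart from any other difference between the labelled samples.

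CPEB4 was not higher on the array labelled with it. Probe sets that lie outside the introduced sequence are a candidate explanation, and 0 of the CPEB4 probe sets had a position in the sources used, so this stays open. Swapped labels are open too: the brightest probe set differed by −0.22, which lies within the central 95% of genes of similar brightness and decides nothing while the positions are unknown. No biological explanation of the CPEB4 values was tested.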

How the results depend on the processing

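Of the alternatives, the choices of bright interferon members (median 1.66 for the 24 with a high mean over both arrays, a choice that the difference itself enters), the extremes under the stricter filter and the lists without shared members were chosen after the data were seen. The counts of genes past 2-fold, 487 higher and 527 lower, depended on how dim values were treated. They were 1761 and 1875 with no dim filter, 40 and 14 under the stricter filter, and 103 and 79 with a pseudocount of 64. Other size rules gave 1126 and 1137 genes at 1.5-fold and 266 and 266 at 3-fold. Quantile normalization, median centring, loess, the mean over probe sets, removal of _x_at and _s_at probe sets, agreement of all probe sets and a pseudocount of 16 stayed within 1.5 times the original counts. Scaling changed few calls: loess shared 479 of the higher and 523 of the lower genes.

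The number of lists outside their random lists, 14, was 6 without _x_at and _s_at probe sets, where fewer genes are measured, and 8 with random lists not matched on brightness. In each of these, 6 of the 14 were kept, and the unmatched random lists added the colon differentiation and endothelial lists. Unmatched random lists do not carry the trend with brightness and also draw on dim genes, whose differences spread more widely, and these reasons were not told apart. Removal of _x_at and _s_at probe sets also put the NF-kB (0.25), NRF2 (−0.09), ribosomal (−0.10), proteasome (0.07), respiratory chain (0.06) and glycolysis (−0.20) lists inside, with their directions kept. No dim filter added colon differentiation, the stricter filter heat shock, and the mean over probe sets YAP and TGF-beta targets. The interferon, G1/S, hypoxia and immediate early lists stayed outside in all 8 alternatives. Median centring, which kept all 14 lists outside, moves all genes alike and is no separate check in these counts. Without the genes they share with another such list, all 14 lists were still outside. The gap between probe sets was 0.44 without the dim filter, against 0.27 with it. CPEB4 kept its direction under quantile normalization (−0.25), median centring (−0.23) and loess (−0.23).

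Of the named genes, 929 values moved by less than the gap between probe sets in their own brightness group (0.53, 0.28 or 0.16), 114 moved by more and 3 reversed, where only genes past 2-fold in the main analysis could count as reversed. The reversals were SLC4A9 at −0.55 and ZIC4 at 0.12 without the dim filter, and ERAP1 at −0.60 without _x_at and _s_at probe sets; in each case another probe set of the gene was used. For the list medians the measure was the width of the central 95% of the random lists divided by 4, by which 219 were stable and 33 moved, and a turn of direction in a list that lay inside was not counted as a reversal. Signal over background limits the dim genes, and no alternative replaces a second array of each group.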

Other observations

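The tests on mitochondrial genes and on interferon ligands, receptors and kinases were chosen after results were seen, and the gamma-leaning list was written before its own values were seen. Transcripts of interferon lambda, a type III interferon made by epithelial cells, were higher on the array labelled HCT116-CPEB4. IFNL1 read 52.7 on the HCT116-GFP array, under the dim filter, and 146.9 on the other, and IFNL2 read 77.0 and 404.4. The type I interferon transcripts examined (IFNA1, IFNA2, IFNB1, IFNE, IFNK and IFNW1) were under the dim filter on both arrays. The type II transcript IFNG was under it too. IFNB1 read 4.82 and 5.81, IFNA1 read 21.7 and 16.5, and IFNG read 8.34 and 34.5. Values of other IFNA genes were not examined. At the brightest probe sets of the receptors, IFNAR1 differed by 0.06 (its 4 probe sets ran from −0.35 to 0.27), IFNAR2 by 0.18 (−0.20 and −0.44 at its others), IFNLR1 by −0.13, IL10RB by −0.13, IFNGR1 by −0.12 and IFNGR2 by −0.49, and the list of ligands, receptors and kinases had a median of −0.03 over 10 genes (percentile 39.6). In the gamma-leaning list, 11 of 18 genes were measured, 7 above 0 and 4 below, and their median lay at percentile 79.5. The dim GBP3 differed by 1.72, the dim CIITA by 0.93, GBP2 by 0.46 and WARS1 by 0.44. CD274 differed by 0.22 and IDO1 by 0.09, and HLA-DRA by −0.50 with 1.39 at its other probe set.

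Genes encoded in the mitochondrial genome were higher on the array labelled HCT116-CPEB4. Of 7 measured genes 6 lay above 0, with a median of 0.32 (percentile 99.97). ND6 differed by 0.64, COX3 by 0.60, COX1 by 0.39 and ATP6 by 0.32, and COX2 was lower (−0.12). The probe sets used for COX1, COX3, ATP6, ND2 and ND4 are marked _x_at or _s_at. Those of ND6 and COX2 are not, and these genes differ in direction. The median was 0.37 after quantile normalization, when all 7 lay above 0, and 0.36 after loess. The poly(A) spike-ins were higher on the same array by a median of 0.42.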
